A study of uncultured marine bacterium with 6 samples.

How the data were processed

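RNA was sequenced in 6 samples of a marine sediment bacterial consortium that the submitters name GLY. The 3 treated libraries are labelled as exposed to domoic acid at 1 mg/L for 7 days, and the 3 control libraries as untreated. The labels give no sampling day for the untreated libraries. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit from total RNA. An rRNA depletion step, the strand setting, the counting tool and the assembly are not given in the sources used here. Per the submitters' processing notes, the tools include Bowtie 0.12.2 and the genome build mm8. That build is a mouse assembly, while the identifiers in the files have the form c4114_g1 and are not mouse genes, so no coordinates are reported.

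Each library has 1 deposited file with an estimated count and an FPKM value for the same 18574 identifiers, here called genes. Whether an identifier holds 1 gene or several is not given. The deposited values headed as read counts are expected counts: between 99.1% and 99.4% of them per library lie within 0.005 of a whole number and the rest carry fractions. The deposited FPKM values are fragments per kilobase of a gene scaled by the library total, per the file headers. Count and FPKM together imply an effective length for each gene, count × 1000000000 / (FPKM × library total), taken from the library with the highest FPKM where that was at least 0.5. This gave a length for 17884 genes, and the lengths of one gene in different libraries differed by a median of 0.00085 on the log2 scale. The files pair the identifiers with no gene names, products or organisms. The 22 gene lists fixed before the data were examined therefore matched nothing, the planned list tests were not run, and rRNA was not separated. For the same reason 2 genes that rose and 2 that fell are named, by a rule fixed in advance: adjusted p below 0.05, no overlap of the groups in CPM (counts scaled by the library total), a mean of at least 50 reads in the higher group, and the largest fitted fold change in each direction.

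Library totals ran from 20362233 to 28750412 estimated reads. Counting intervals and floors cover counting error only, since reads are not independent molecules. The floor for a gene with 0 reads is 3 reads over the pooled libraries of a group. For genes detected at a common depth, each library was thinned to 20362234 reads, the smallest total after rounding, with the exact hypergeometric expectation. Single values per library were compared with an exact permutation test of the difference of means, two-sided. With 3 libraries against 3 its smallest p is 0.1, so no such comparison can pass 0.05. The labels do not say whether replicates were separate cultures, so all p-values measure the spread between these libraries, which may be technical.

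Expected counts were rounded to whole numbers. The main comparison used edgeR 4.0.16 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment, adjusted p below 0.05) on all 6 libraries with group as the only term; the plan had assumed raw counts. Standard errors of fold changes were taken as the absolute log2 fold change over the square root of the F statistic. Alternatives were RLE factors, library totals, no filter, a mean of at least 50 reads in one group, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1), a log2 fold change of at least 1, a replicate block and leaving out each library. TMM with singleton pairing was added after seeing the data.

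Genes were also sorted into covariation groups, a step chosen after seeing the data. It took the 3546 genes with a mean of at least 200 reads, which held 98.6% to 99.4% of the reads of each library. For each gene, log2 CPM with 0.5 reads added were centred within the treated libraries and within the untreated libraries. For genes with ample reads in every library, these deviations between replicates hold no information on the difference between the 2 treatment groups. For a gene with few or no reads in a whole group, they are largely set by the added reads and the library totals. There they reflect its low level in that group. They were clustered with HDBSCAN in scikit-learn 1.9.0 (at least 100 genes, min_samples 10), and the groups were numbered by their number of genes. Within 3 of the groups, those with a median of at least 10 reads per gene in every library, edgeR was run again with the group's own library totals and TMM factors, with adjustment over the 1203 genes. Genes called there differ relative to their group. Because the groups were built from the deviations between replicates that also give this test its error term, the spread within a group is reduced by the selection and the p-values may be too small. As an alternative, the same clustering was run on deviations from the mean of all 6 libraries, which does not use the treatment labels, and selects on the treatment difference and on the differences between replicates alike.

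The scripts were tested on simulated data. With 200 of 7740 genes changed and the dispersion set to 0.1, the main test recovered 80% of 4-fold changes and 100% of 16-fold changes, with 7 calls among 7540 unchanged genes. With the dispersions estimated from these libraries it recovered 0% at 4-fold, 16-fold, 64-fold and 256-fold, with 0 calls among unchanged genes. Within the gene groups, 98% of 2-fold and 100% of 4-fold changes were recovered among 1203 genes, with 17 calls among 1003 unchanged genes. That simulation kept the groups fixed, used the dispersions estimated in them and did not repeat the clustering. It therefore does not test the effect of the selection, and its recovery may be too high. The grouping found 6 groups in 2000 simulated genes with 6 shared profiles and 0 groups in 2000 independent genes. All CPM values are relative: when some genes take up more of a library, all others go down in it. R 4.3.3 and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used.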

Results

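Gene expression was measured by RNA sequencing in a bacterial consortium from marine sediment, with and without domoic acid. Domoic acid is a neurotoxic amino acid made by some marine diatoms and is related in structure to glutamate. The treated group held 3 libraries from consortium kept with 1 mg/L domoic acid for 7 days, and the control group held 3 untreated libraries. The treated libraries had 24727174, 20362233 and 20566221 estimated reads and the untreated libraries 24137880, 25570757 and 28750412, spread over 18574 assembled genes known by identifier only. The comparison of the 2 groups asks how the consortium's transcript pool differs after exposure to the toxin. Since no sampling day is labelled for the untreated libraries, a difference in sampling time cannot be told apart from an effect of domoic acid.

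Fewer genes were detected after domoic acid. Thinned to the smallest library, the treated libraries held reads from 9260.2 ± 1733 genes and the untreated libraries from 14437 ± 326 (mean ± SD, n = 3 each, exact permutation p = 0.1, the smallest the design allows). The treated libraries ranged from 7875 to 11204 genes and the untreated ones from 14211 to 14811, so the groups did not overlap. As deposited, 419 genes had at least 10 reads in every untreated library and none in any treated library, while 3 genes showed the opposite. The numbers were 2846 and 89 with at least 1 read, and 17 and 2 with at least 50 reads. Reads were also more concentrated. The 10 most abundant genes of each library took 20.9% ± 2.76 of the reads with domoic acid and 12.2% ± 0.262 without it (SD, n = 3 each, exact permutation p = 0.1). The single most abundant gene took 9.47%, 6.47% and 4.55% of the treated libraries and 2.20%, 2.63% and 1.54% of the untreated ones. The 100 most abundant genes differed less in ratio, at 53.3% ± 3.51 with domoic acid and 46.6% ± 2.56 without it (SD, n = 3 each, exact permutation p = 0.1). As rRNA was not separated, whether the most abundant genes include it is not known.

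**Figure D1:**
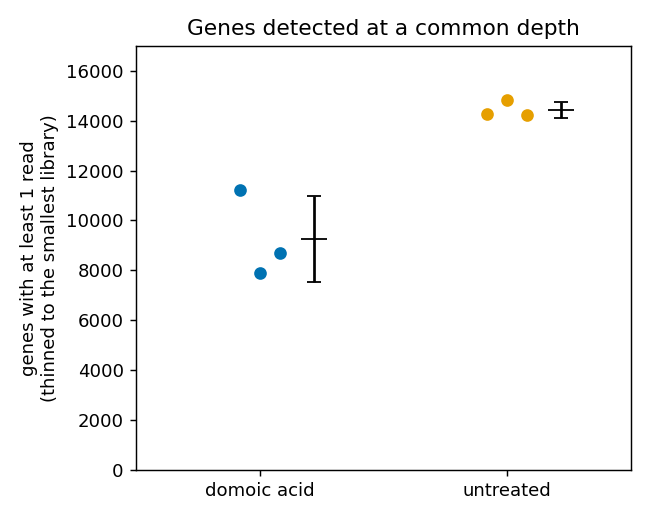
Number of genes with at least 1 read after thinning each library to the smallest library total (vertical axis), for the domoic acid and untreated groups (horizontal axis). Points are libraries, and the bar beside them is the mean with its SD (n = 3). The treated libraries lie between 7875 and 11204 genes, all below the untreated libraries.

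Treated libraries had less in common with one another than untreated libraries did, in each of the 3 pairs per group. Counting for each gene the smaller of its shares in the 2 libraries, pairs of untreated libraries had between 72.4% and 86.3% of their reads in common. Pairs of treated libraries had between 27.6% and 43.4% in common, and pairs across the groups between 7.12% and 39.8%. Spearman correlations across genes, which are not independent replicates, ran from 0.75 to 0.84 among untreated pairs, from 0.54 to 0.74 among treated pairs and from 0.16 to 0.64 across groups. Domoic acid replicate 1 gave the highest values across the groups, a correlation of 0.64 with untreated replicate 1 and 39.8% of reads in common with untreated replicate 2. With 3 libraries per group, the difference in spread was not tested.

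In the main test, the genes called between the groups were mostly rare transcripts with reads in the untreated libraries and few or none after domoic acid. This depended on the tool, since DESeq2 and limma called many abundant genes as well, as given further below. In the simulation with the dispersions estimated from these libraries, the main test recovered 0% of the changed genes at every fold change simulated. The scarcity of abundant genes among its calls therefore does not show that abundant genes were unchanged. Of 7740 genes tested, edgeR's quasi-likelihood test called 13 higher and 575 lower with domoic acid at an adjusted p below 0.05. Of the 575 lower genes, 398 had no read in any treated library, and 452 had a mean under 50 reads in the untreated ones. Together the 575 genes took 0.0973% ± 0.0487 of the untreated reads and 0.000261% ± 0.000317 of the treated reads (SD, n = 3 each). The 13 higher genes took 0.00406% ± 0.00256 of the treated reads. The gene c4114_g1, with an implied effective length of 689 bases, had 93, 56 and 118 reads in the treated libraries and 0 in each untreated library, at least 106-fold higher against a floor of 3 reads over the group. Its fitted log2 fold change was 10.51 ± 2.82 (SE, edgeR adjusted p = 0.0296). The gene c5245_g1 (1182 bases) had 54, 67 and 169 treated reads and 0 untreated reads, at least 116-fold higher, with a fitted log2 fold change of 10.36 ± 2.74 (SE, edgeR adjusted p = 0.0274). In the opposite direction, c7791_g1 (2187 bases) had 212, 1623 and 594 reads in the untreated libraries and 0 in each treated library, at least 678-fold lower. Its fitted log2 fold change was -12.61 ± 3.49 (SE, edgeR adjusted p = 0.0359). The gene c11161_g1 had 76, 1256 and 308 untreated reads and 0 treated reads, at least 457-fold lower, with a fitted log2 fold change of -12.07 ± 3.45 (SE, edgeR adjusted p = 0.0445). These fitted values depend on the prior count, and the annotation and function of the 4 genes are not given in the files. The calls of the 4 genes held in only 6 or 7 of 14 alternative settings.

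The number of calls depended on the scaling, the count filter, the tool, a replicate block and single libraries. With the replicate number as a block, edgeR called 0 genes higher and 0 lower (1165 at an unadjusted p below 0.05). With no low-count filter edgeR called 0 genes higher and 0 lower (6542 at an unadjusted p below 0.05), and with a filter of a mean of at least 50 reads in one group it also called 0 and 0 (2481 at an unadjusted p below 0.05). The tested genes had a median log2 fold change of -0.37 with TMM, -0.93 with RLE and -1.32 with library totals. RLE gave 132 higher and 1094 lower genes, library totals gave 95 and 1764, and limma on log2(FPKM + 1) gave 483 and 3055. DESeq2 called 2179 higher and 2392 lower genes, so that 47.7% of its calls were higher with domoic acid, against 2.21% in edgeR with TMM, 5.11% with library totals and 10.8% with RLE. Leaving out domoic acid replicate 1 gave 72 higher and 3126 lower genes, and leaving out domoic acid replicate 3 gave 43 and 304. Without untreated replicate 2 there were 0 higher and 570 lower genes, with 1918 genes at an unadjusted p below 0.05. Without domoic acid replicate 2, untreated replicate 1 or untreated replicate 3, edgeR called 0 genes, with 2109, 2451 and 1534 genes at an unadjusted p below 0.05. Without any fold or spread model, every treated library lay below every untreated library in CPM (counts scaled by the library total) for 3471 of the 7740 genes (44.8%) and above for 934 (12.1%), where chance gives 5% in each direction for independent genes. The lower genes also outnumbered the higher ones with TMM (2650 against 854) and RLE scaling (3260 against 1549).

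Most of the abundant transcripts fell into 7 groups of genes that moved together, and each treated library was dominated by a different one. The groups were built from the differences between replicates, in a step chosen after seeing the data, and they took in 2902 of the 3546 genes with a mean of at least 200 reads. For genes with few or no reads in a whole treatment group, these differences reflect that low level. Other settings of the grouping gave 5 to 9 groups. Group 2 (601 genes) took 63.9% of the reads of domoic acid replicate 1, group 3 (565 genes) took 63.6% of replicate 2, and group 1 (657 genes) took 49.97% of replicate 3. Group 2 was also abundant in the other treated libraries, at 20.1% and 32.2%, and took 3.35%, 23.7% and 6.21% of the untreated ones. Group 3 took 12.3% of domoic acid replicate 1 but 0.265% of replicate 3, and at most 1.34% of an untreated library. Group 1 took 2.96% and 5.01% of the other treated libraries and at most 1.06% of an untreated one. Without the library it dominated, the mean difference of treated minus untreated shares went from 18.9 to 3.59 percentage points for group 1, from 27.7 to 15.1 for group 2 and from 24.9 to 5.83 for group 3. For group 3 it was 37.5 without domoic acid replicate 3.

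**Figure D2:**
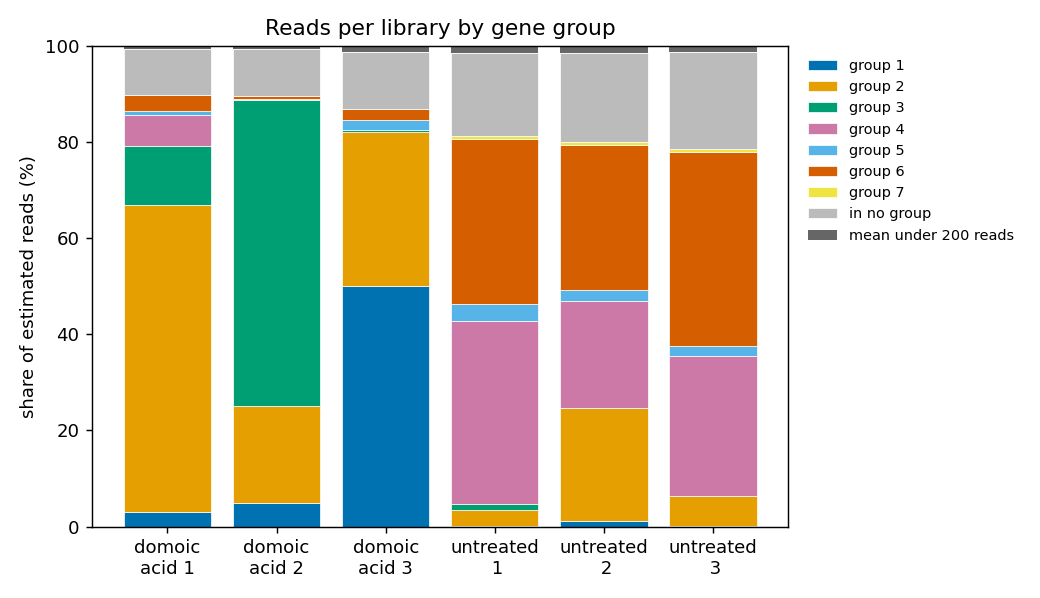
Share of estimated reads in percent (vertical axis) taken in each of the 6 libraries (horizontal axis) by the 7 gene groups, by genes in no group and by genes with a mean under 200 reads. Groups 4 and 6 make up most of each of the untreated bars, whereas group 2, group 3 and group 1 make up the largest part of domoic acid replicates 1, 2 and 3.

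Groups 4 and 6 were abundant in each untreated library. Group 6 (275 genes) took 35.0% ± 5.15 of the untreated reads and 2.11% ± 1.33 of the treated reads (SD, n = 3 each, exact permutation p = 0.1). The difference of treated minus untreated shares was -32.9 percentage points in reads and -19.6 in FPKM, which takes out gene length. Group 4 (351 genes) took 38.1%, 22.2% and 29.3% of untreated replicates 1, 2 and 3, and 6.42%, 0.109% and 0.00566% of domoic acid replicates 1, 2 and 3. The untreated libraries differed in other groups: group 2 took a larger share of untreated replicate 2 than group 4 did, the share of group 1 ran from 0.0516% to 1.06% and that of group 3 from 0.00221% to 1.34%. Group 7 (126 genes) took 0.543% ± 0.0710 of the untreated reads and 0.0195% ± 0.0330 of the treated reads, nearly all of the latter in domoic acid replicate 1. Group 5 (327 genes) took 2.64% ± 0.789 of the untreated and 1.04% ± 1.02 of the treated reads, and its groups of libraries overlapped (exact permutation p = 0.2). The exact permutation p was 0.1 for groups 1, 4, 6 and 7 and 0.2 for groups 2, 3 and 5, and after Benjamini-Hochberg adjustment over the 7 groups it was 0.175 and 0.2. The 644 genes in no group took 10.3% ± 1.22 of the treated and 18.7% ± 1.40 of the untreated reads.

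Most genes of a group had similar fold changes, among the genes with a mean of at least 200 reads that were grouped. The SD of the fold changes was between 0.353 and 0.748 on the log2 scale in 6 of the groups. In group 2 it was 2.52, since 35 of its 601 genes lay over 3 log2 units from the group's median. On the scale of log2 CPM with 0.5 reads added, the median log2 fold change was 6.09 in group 1 (quartiles 5.82 and 6.41), with all 657 genes higher with domoic acid. It was 7.11 in group 3, with all 565 genes higher, and 1.90 in group 2, with 566 genes higher and 35 lower. It was -1.85 in group 5 (327 of 327 genes lower), -4.49 in group 6 (275 of 275), -7.38 in group 4 (351 of 351) and -7.90 in group 7 (126 of 126). Values for groups 1, 3, 4 and 7 depend on the 0.5 reads added, since some libraries held few or no reads per gene. As means of logs they also give more weight to libraries with a low share: the log2 ratio of the mean treated over the mean untreated share was 5.62 for group 1, 1.81 for group 2, 5.79 for group 3, -3.78 for group 4, -1.35 for group 5, -4.05 for group 6 and -4.80 for group 7, closer to 0 in each. The group to which a gene belonged accounted for 94.7% of the variance of these fold changes among the 2902 genes placed in a group. The 644 genes in no group, with an SD of 4.15, were left out of this value. For groups with few or no reads in some libraries, the grouping may in part reflect the level in a treatment group. Of the 2899 genes of the 7 groups that were tested, edgeR called 0 with TMM, with 1015 at an unadjusted p below 0.05 and a common dispersion of 2.04. It called 65 with RLE and 158 with library totals, while DESeq2 called 2072 and limma on log2(FPKM + 1) called 1151.

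**Figure D3:**
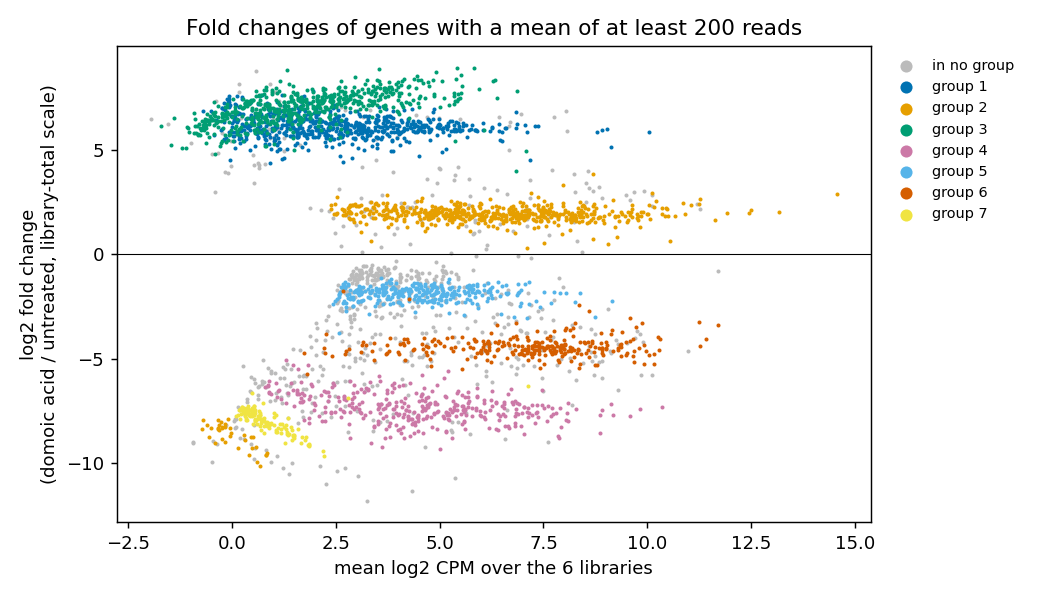
Log2 fold change of domoic acid over untreated libraries on the library-total scale (vertical axis) against mean log2 CPM over the 6 libraries (horizontal axis). Each point is 1 of the 3546 genes with a mean of at least 200 reads, coloured by gene group, with genes in no group in grey. Most genes of a group lie in a band, with medians from -7.90 to 7.11, while 35 genes of group 2 lie far below its band and the genes in no group are scattered (SD 4.15).

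Abundant genes were long assembled sequences, within the groups and outside them. Such a sequence may hold more than 1 gene, so gene counts, fold changes and calls here refer to identifiers. The median implied effective length ran from 3.98 kb in group 5 to 7.62 kb in group 6, and the longest gene was 73.3 kb, in group 3. The 644 abundant genes in no group had a median of 3.65 kb, a longest gene of 27.4 kb and a summed length of 3.14 Mb. Summed over a group, the lengths came to 3.38 Mb in group 1, 3.32 Mb in group 2, 3.79 Mb in group 3, 2.27 Mb in group 4, 1.60 Mb in group 5, 2.66 Mb in group 6 and 0.665 Mb in group 7. The much rarer 575 genes called lower had a median length of 0.857 kb and the 13 called higher of 1.07 kb.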

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

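Chosen after seeing the data were the gene groups and all settings of the grouping and of calls within groups, the other thresholds for detected genes, leaving out single libraries for detected genes and shares, and TMM with singleton pairing. The higher and lower calls of the main test numbered 13 and 575, as they did with a log2 fold change of at least 1. RLE gave 132 and 1094, library totals 95 and 1764, DESeq2 2179 and 2392, limma on log2(FPKM + 1) 483 and 3055, and TMM with singleton pairing 54 and 938. DESeq2, library totals and RLE included 588, 588 and 584 of the 588 genes of the main test. With no low-count filter, or with a mean of at least 50 reads in one group, edgeR called 0 higher and 0 lower genes (6542 and 2481 at an unadjusted p below 0.05); the cause was not tested. Leaving out 1 library gave 0 to 72 higher and 0 to 3126 lower genes. The TMM factors of the treated libraries were 0.311, 2.41 and 0.867, and their RLE factors 0.663, 0.523 and 1.48. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.29, -0.31 and 0.31, and only domoic acid replicate 1 correlated best with its own number, while domoic acid replicate 2 correlated at 0.72 with untreated replicate 1 and domoic acid replicate 3 at 0.68 with untreated replicate 2. With the replicate number as a block, edgeR called 0 higher and 0 lower genes, with 1165 at an unadjusted p below 0.05. The 4 named genes stayed past the threshold in 6 or 7 of 14 alternatives. They kept their direction in all 14, which carries no weight, since each had 0 reads in every library of one group. The difference in detected genes at the common depth was -5177, and -2485 for genes with at least 10 reads as deposited; without 1 library it ran from -6149 to -4484. The 10 most abundant genes took 8.75 percentage points more in the treated libraries, and 9.77 in FPKM. Among the genes placed in a group, the gene groups explained 94.7% of the variance of fold changes. The value was 83.3% when they were made from the untreated libraries alone, and between 88.9% and 95.6% under the other 5 settings. The number of groups was 7, and 8 or 9 with a mean of at least 100 or 50 reads, 8 with groups of at least 40 genes and 5 from the untreated libraries alone. The differences in group shares kept their sign in all 49 alternatives, but in FPKM that of group 6 went from -32.9 to -19.6 percentage points and that of group 7 from -0.524 to -0.750. For groups 1, 4, 6 and 7, treated and untreated shares did not overlap. Leaving out 1 library could not change the sign there, so those outcomes carry no weight. Relative to their gene group, 48 genes were called higher and 90 lower; groups made without the treatment labels gave 0 and 0 in edgeR (275 at an unadjusted p below 0.05) and 75 and 92 in DESeq2; in the first groups DESeq2 gave 85 higher genes, leaving out the genes over 3 log2 units from their group's median, 35 of them among the lower calls, gave 24 and 38, and leaving out 1 library gave 10 to 111 and 56 to 156. The gene list tests and scaling by named organism were not run, since the files name neither. At this depth a gene with 0 reads in a whole group could still hold up to 0.0457 CPM with domoic acid or 0.0382 without it.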

Other observations

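The fits within gene groups, and the tests of groups made from the untreated libraries alone or without the treatment labels, of summed length, of genes far from their group's median and of other splits of the libraries, were chosen only after the results they bear on were seen.

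Calls of abundant genes relative to their own gene group depended on how the groups were made. In groups 2, 5 and 6, which had enough reads in every library, edgeR called 48 genes higher and 90 lower than their group, of 1203 tested (adjusted p below 0.05). These groups were built from the same deviations between replicates that serve as the error of the test, so the selection itself tends to lower their common dispersions (0.0386, 0.0162 and 0.0191, against 2.04 in the whole consortium) and the adjusted p-values. Made without the treatment labels, the corresponding groups shared 565, 322 and 263 genes with groups 2, 5 and 6 and had dispersions of 0.0759, 0.0224 and 0.0230. In them edgeR called 0 of 1294 genes, with 275 at an unadjusted p below 0.05, and DESeq2 called 75 higher and 92 lower. That grouping also selects against genes that differ from their group between treatments, so it does not show that there are none. In the first groups the calls also moved with single libraries and with a few genes. Group 2 had 5 higher and 46 lower genes, and 35 of the lower ones lay over 3 log2 units from the group's median. Leaving those 35 genes out changed the calls among the other genes from 48 higher and 55 lower to 24 and 38. Without domoic acid replicate 3 the counts were 111 and 156, without domoic acid replicate 2 they were 28 and 60, and without untreated replicate 1, 2 or 3 they were 15 and 71, 14 and 62, and 10 and 56. Whether genes changed relative to their group is therefore left open.

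Most fold changes of abundant genes fell into bands shared within groups of 126 to 657 genes. Gene length explained 0.814% of the variance over all abundant genes, including the 644 in no group, which argues against length bias. The groups explained 99.2% among their own genes with a mean of at least 2000 reads. That value leaves out the genes in no group. A mean of at least 2000 reads over the 6 libraries does not ensure reads in each of them. Over all genes of groups 1, 3, 4 and 7, the lowest library median was 4, 0, 1 and 0 reads. For these groups the value therefore does not decide whether low counts shaped the fold changes. In groups 2, 5 and 6 that median was 362, 60 and 310 reads. A candidate explanation is that each group is the genome of 1 member, or of close relatives, whose share of the consortium differed between libraries. Groups made from the untreated libraries alone explained 58.5% of the variance between the treated libraries, among the genes they held. In 100 random reassignments the highest value was 0.433%. Any movement shared among genes could exceed that value, so this comparison does not favour member genomes over other causes of shared movement. Genes of groups 1 and 3 also had few or no reads in some untreated libraries. Deviations of such genes are set in part by the added reads, so the 58.5% may partly reflect a low level without domoic acid. The median summed length of a group, 2.66 Mb, does not bear on the explanation by member genomes either, since the 644 genes in no group summed to 3.14 Mb. On that hypothesis most fold changes per gene would follow the make-up of the consortium and not regulation. Whether domoic acid or divergence of separate cultures set the make-up was not tested, and large sets of co-regulated genes within 1 organism stay open as well.

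The loss of detected genes was not removed by depth or by dominance. At a common depth the lowest untreated library still exceeded the highest treated library by 3008 genes. Among the 15672 genes outside the groups, thinned to 2106852 reads, that gap was 2019 genes, which argues against reads being taken up by the dominant groups as the whole cause. A loss of rare members from the treated libraries may account for it, but no test here separated that from lower expression of rare genes.

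The calls relative to the gene group may be genes of another organism placed in the group, in part or as a whole. Those over 3 log2 units from their group's median made up 25.4% of the 138 calls (exact 95% interval 18.3% to 33.5%). The interval takes the calls as independent, but genes of a group move together and all 35 far calls were in group 2. It is therefore too narrow. The share does not bound the misplaced genes either, because the medians of groups 5 and 6 lie 2.64 log2 units apart, less than that distance. Of the 103 other calls, 41 (39.8%) ended when the far genes were left out. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 588 calls in the main test and the highest of the others 0 (at most 575 at an unadjusted p below 0.05), and 1 of 10 splits is too few for a share under 0.05. For calls within groups the real split gave 138 and the highest of the others 0, but the groups were made to agree between the replicates of the real split, which largely fixes that outcome. In the groups made without the treatment labels each of the 10 splits gave 0 calls in edgeR, with 275 genes at an unadjusted p below 0.05 in the real split and at most 110 in the others. Effects of domoic acid and of growth state on these genes stay open and were not tested.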
